A study of Caenorhabditis elegans with 2 samples.

How the data were processed

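Peak lists from anti-GFP chromatin immunoprecipitation of tagged MAB-9 in whole L1 larvae were used, from 2 biological replicates in 1 group, as the labels give them. Per the labels the coordinates are of the ce11 build. Per the file headers each list was derived from alignments of the replicates and a control file, and the thresholded lists had a further input whose nature is not given in the sources used here. The aligner, the peak caller and their versions are likewise not given in the sources used here. The deposited signal of a peak is the value written by the authors' peak caller, on a scale that is not stated, and it was used to describe and rank peaks. The deposited score of a peak follows its irreproducible discovery rate, a measure of how well a peak's rank repeats between lists. The ranked lists hold the −log10 of that rate, per the file headers. All peaks kept in the authors' thresholded lists had a rate of at most 0.01. The conservative list and the other pooled list combine both replicates, and each replicate also has a ranked and a thresholded list. No file used gives read counts, so the depth per sample is unknown and no interval that needs it is given; intervals on shares of peaks treat peaks as independent and do not cover differences between replicates.

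The conservative list was the main set. Gene annotation was Ensembl release 115, and sequence came from the RefSeq assembly of the same build. Peaks were called shared when they overlapped by at least 50% of the shorter peak. Locations were taken at the summit, and each summit was given the nearest protein-coding transcript start, so that of a divergent gene pair only the nearer gene counts as bound. Random placements kept each peak on its chromosome, with 1000 placements. Sequence patterns were searched on both strands in windows of 201 bp around the summit. Control windows were centred 1000 bp to either side and lay over 300 bp from any main summit. GC-matched windows lay at the same distance from starts of genes without a main peak, with GC within 2.5 percentage points and up to 2 per peak. Odds ratios have Woolf 95% intervals, with a constant added when a cell is 0, and two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the patterns, the 6-mers or the lists. Gene lists comprised 15 fixed by symbol and 18 families by name, each with at least 5 members; 6 names matched no protein-coding gene. Matched lists were 10000 random lists in deciles of the length of genome nearest to a gene's start. Medians were compared with 100000 resamples.

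The gene lists, the tests of the report, the alternatives (with 1 exception below) and the rule for named genes were fixed before the data were examined; the 6-mers of AGGTGTGA were singled out afterwards, and further tests chosen afterwards are named in the closing section. Named genes are the nearest gene of the 15 peaks with the highest signal, mab-9, up to 4 bound members with the highest signal of each list past the test, and up to 3 of the T-box, Hox, hindgut and male tail, cholinergic motor neuron, muscle, intestine, and hypodermis and seam lists. Alternatives were another peak list, a stricter threshold, each replicate's own list, other overlaps, windows, controls and gene assignments. Leaving out main peaks that overlap a stronger one was added after seeing the data.

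The code was tested on simulated data. Of 139 windows given a planted AGGTGTGA, 139 were found. At randomly placed peaks 0 of the 6-mers were called, and with bound genes drawn at random 0 of 33 lists were. The overlap step found 404 shared peaks where 400 had been made to overlap. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.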

Results

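MAB-9 is a T-box transcription factor of Caenorhabditis elegans, known for its role in the hindgut and male tail and in motor neurons. Its genomic binding was profiled by chromatin immunoprecipitation and sequencing in whole L1 larvae of strain RW12257, in which the endogenous mab-9 gene carries a TY1, EGFP and 3xFLAG tag. Larvae were synchronised by bleaching and starvation, collected at 6 hours, and the tagged protein was pulled down with an antibody against GFP. There is 1 group with 2 biological replicates, from separate biosamples. The deposited files are peak lists without read counts, so the depth of each replicate is unknown. Control libraries and binding profiles of other factors were not analysed here. The conservative list, with 1431 peaks, served as the main set. The other pooled list held 1492 peaks, and the replicates' own lists held 824 peaks in replicate 1 and 869 in replicate 2.

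The first comparison asked how well the replicates matched. Of the peaks of replicate 1, 564 of 824 (68.5%, exact binomial 95% interval 65.1 to 71.6%) were shared with replicate 2. In the other direction, 564 of 869 peaks of replicate 2 (64.9%, interval 61.6 to 68.1%) were shared with replicate 1. Random placement of the same peaks on their chromosomes gave 0.283% and 0.252% on average (one-sided permutation p = 0.000999 for both, the smallest that 1000 placements can give). The placements did not keep the share of peaks at promoters, so agreement beyond a shared preference for promoters was not tested. Across the 1346 main peaks matched in both replicates' ranked lists, the signal correlated with a Spearman rho of 0.688 and a Pearson r of 0.825 on the log2 scale. These correlations are across peaks, which are not independent replicates. The signals of the replicates lay within 2-fold of each other at 96.9% of these peaks, with an SD of 0.43 of the log2 ratio. Main peaks had been kept for ranks that repeat between lists, so the correlations and this share were partly selected for. They do not measure agreement over all ranked peaks. Of the 1431 main peaks, 560 (39.1%) were in both replicates' thresholded lists and 492 (34.4%) were in neither.

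**Figure D1:**
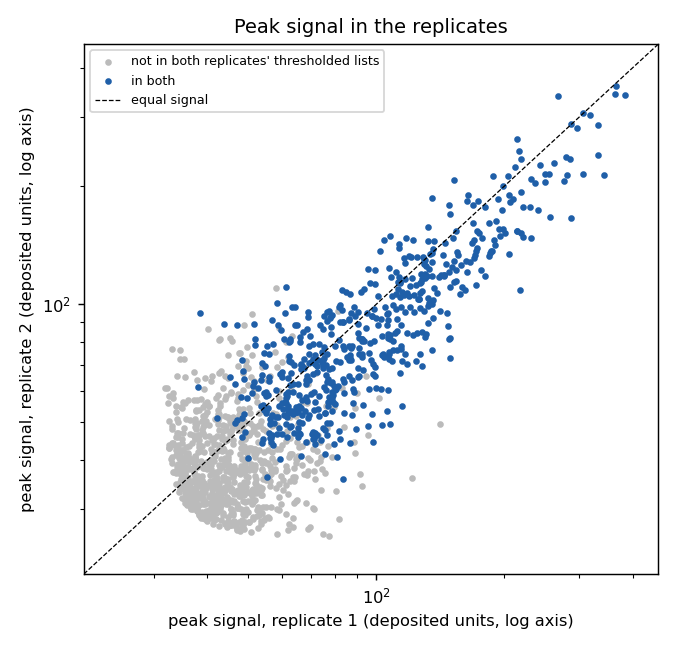
Peak signal of replicate 1 (x axis) against replicate 2 (y axis), in the deposited units on log axes, for each of the 1346 main peaks matched in both ranked lists. Blue points are in both replicates' thresholded lists and grey points are not; the dashed line marks equal signal, and the Spearman rho over all points is 0.688.

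Within the conservative list, the strongest peaks lay mostly at promoters. All 15 peaks with the highest signal were in both replicates' thresholded lists, and 10 of the 15 were promoter peaks. Coordinates are of the ce11 build. The peak with the highest signal, 721 (384 in replicate 1 and 342 in replicate 2), lay in an intergenic region of chromosome V from 14055084 to 14055341, 2605 bp upstream of F58D12.3 (WBGene00010250). The next lay on chromosome III from 3867465 to 3867678, 288 bp upstream of rpl-3 (WBGene00004414), which encodes a large subunit ribosomal protein, with a signal of 719 (365 and 359 in the replicates). A peak on chromosome II from 14561746 to 14561964 lay 245 bp upstream of mog-4 (WBGene00003392), which encodes a DEAH-box helicase, with a signal of 712 (365 and 342). The peak on chromosome III from 7854578 to 7854791, 444 bp upstream of the ribosomal protein gene rpl-35 (WBGene00004449), had a signal of 624 (306 in each replicate). The peak on chromosome III from 10759137 to 10759375 lay 54 bp upstream of tasp-1 (WBGene00010480) and had a signal of 623 (318 and 303). The remaining 10 peaks had signals from 505 to 607. Of these, 6 were promoter peaks, those of F44E5.4, Y22D7AL.10, Y17G9B.5, cox-5A (a cytochrome c oxidase subunit), cnk-1 and cdc-48.1 (an AAA ATPase). The other 4 were intergenic, with K08F11.1, ZK1248.17, W02H3.3 and K02D3.1 as the nearest genes. The ZK1248.17 peak, on chromosome II from 5844717 to 5844926, lay within 200 bp of sls-2.1, an SL2 spliced leader RNA gene.

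The mab-9 gene itself (WBGene00003106, chromosome II, 516024 to 521635, plus strand) carried a peak of modest signal at its start. The peak ran from 515765 to 516084, with its summit 99 bp upstream of the gene, and its signal of 78.5 ranked 1054 of 1431. In the replicates' ranked lists the signal there was 42.03 and 29.3, and neither replicate's thresholded list held this peak. The other pooled list held no peak there either; its peak nearest the gene had a signal of 64 and its summit 1125 bp upstream. A second main peak, from 512005 to 512324, had a signal of 108, and replicate 2's thresholded list held a peak there too.

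Peaks were concentrated at gene starts and at tRNA genes, snoRNA genes and the pooled class of other noncoding RNA genes. Promoter summits, from 1000 bp upstream to 250 bp downstream of the nearest protein-coding start, made up 795 of 1431 (55.6%, exact 95% interval 52.9 to 58.1%), 2.23 times the mean of random placements. The promoter share was 61.7% ± 0.604 (SD, n = 2) in the replicates' own lists. Exons held 4.33% of summits and introns 14.3%, against 22.2% and 28.1% of random placements. Summits within 200 bp of tRNA genes numbered 48 (3.35%), 12.2 times the random mean. Summits within 200 bp of snoRNA genes numbered 43 (3.00%), 16.2 times the random mean. Other noncoding RNA genes lay within 200 bp of 263 summits (18.4%), 2.65 times the random mean. Each of these 6 differences had a two-sided permutation p of 0.000999, the smallest that 1000 placements can give, and an adjusted p of 0.00133 over 8 classes. The intergenic share of 25.8% did not differ detectably from the 24.7% of random placements (permutation p = 0.337, adjusted p = 0.385). Promoter, exon, intron and intergenic are exclusive classes with promoters assigned first, so the promoter excess lowers the other shares. How summits outside promoters divide among the other classes was not compared with the placements. No summit lay within 200 bp of an rRNA gene (0 of 1431, upper exact 95% bound 0.257%). Random placements gave 0.0173% on average, too few to show a deficit. A summit could count both at a promoter and at an RNA gene. The placements did not hold the promoter share fixed, so a concentration at RNA genes apart from promoters was not tested. Promoter peaks had a higher median signal than other peaks, 110.2 against 88.8 (permutation p = 1e-05, the smallest that 100000 resamples can give).

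**Figure D2:**
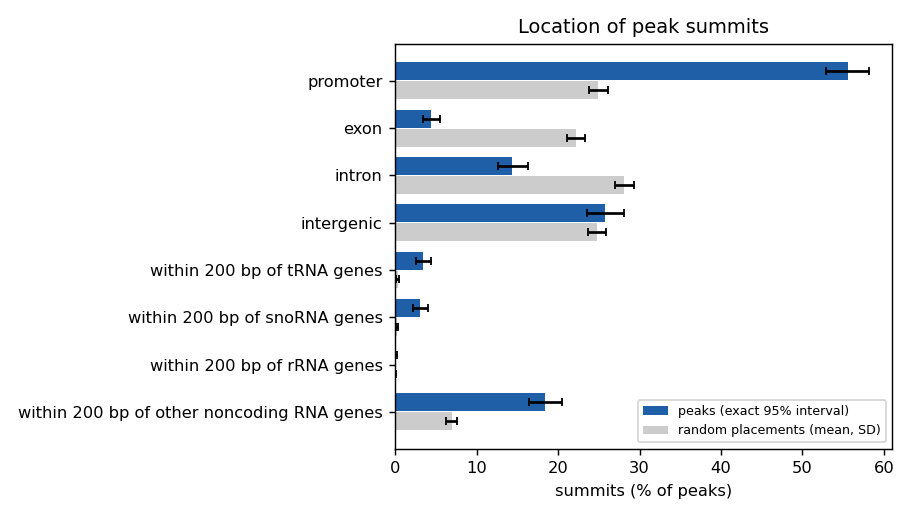
Share of peak summits (x axis, % of peaks) in each location class for the 1431 main peaks (blue, exact 95% interval) and for 1000 random placements (grey, mean and SD). The promoter share of 55.6% exceeds that of the random placements, and the exon share of 4.33% lies under it.

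Peaks were denser on chromosomes I and III and sparser on V. Chromosome III held 268 peaks (18.7%, exact 95% interval 16.7 to 20.9%) with 13.7% of the genome (exact binomial adjusted p = 4.93e-07). Chromosome I held 251 (17.5%) with 15.03% of the genome (exact binomial adjusted p = 0.0191). Chromosome V held 210 (14.7%) with 20.9% of the genome (exact binomial adjusted p = 1.43e-08). The X chromosome held 267 peaks (18.7%, interval 16.7 to 20.8%) with 17.7% of the genome, which was not a detectable difference (two-sided exact binomial p = 0.332, adjusted p = 0.398 over 6 chromosomes). The share on X was 16.6% and 16.9% in the replicates' own lists, on the other side of the genome share, and also without a detectable difference.

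The next comparison asked whether the peaks carried the sequence that T-box proteins bind. AGGTGTGA lay within 100 bp of the summit at 3 of 1431 peaks (0.210%), against 13 of 2782 flanking windows (0.467%). The odds ratio was 0.447 (95% interval 0.127 to 1.57), with no enrichment detected (two-sided Fisher's exact p = 0.291, adjusted p = 0.340 over 15 patterns). The odds ratio was 0.973 in replicate 1's own list and 0.493 in replicate 2's, with no enrichment detected in either (Fisher's exact p = 1 and 0.669), and 0.978 among the stronger peaks by signal. The shorter core AGGTGT lay in 4.96% of peaks and 5.43% of flanks (odds ratio 0.910, Fisher's exact p = 0.561), and against windows matched on GC it was less frequent in peaks (odds ratio 0.659, Fisher's exact adjusted p = 0.00732). The other 6-mers of the site were more frequent in peaks than in flanks, GGTGTG at 7.62% against 4.64% (odds ratio 1.70, interval 1.30 to 2.21, Fisher's exact adjusted p = 0.000278 over all 6-mers) and GTGTGA at 10.7% against 7.94% (odds ratio 1.39, interval 1.12 to 1.72, Fisher's exact adjusted p = 0.00712). Neither passed against windows matched on GC (odds ratios 1.003 and 1.202, Fisher's exact adjusted p = 1 and 0.171), among the stronger peaks or in replicate 1's own list (Fisher's exact adjusted p = 0.0781 and 0.281), and in replicate 2's own list GGTGTG passed (Fisher's exact adjusted p = 0.0108) and GTGTGA did not (0.0795). The 3 sites were near tlp-1, scpl-3 and H14E04.3, which are named after their values were seen, being all the sites found. The tlp-1 site, on chromosome IV from 13704229 to 13704236, lies in the promoter, in the sequence GATGAGGAGTAGGTGTGAACGTTACACA, under a peak with a signal of 153 (71.8 and 74.1 in the replicates). The scpl-3 site, on chromosome I from 4298172 to 4298179, also lies in a promoter peak, and the H14E04.3 site, on chromosome III from 2393507 to 2393514, in an intergenic one. The median signal was 108.6 with the site and 98.7 without (permutation p = 0.752), and with 3 peaks this difference could not be resolved.

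Other patterns did separate the peaks from their flanks. The GAGA repeat GAGAGAGA lay in 9.64% of peaks and 2.16% of flanks (odds ratio 4.84, interval 3.55 to 6.60, Fisher's exact adjusted p = 1.30e-24), with odds ratios of 9.01 in replicate 1's own list and 7.14 in replicate 2's. The E-box CACGTG lay in 7.20% and 4.24% (odds ratio 1.75, Fisher's exact adjusted p = 0.00016). The COE pattern, the site of the motor neuron regulator UNC-3 and its relatives, lay in 12 peaks and 3 flanks (odds ratio 7.83, interval 2.21 to 27.8, Fisher's exact adjusted p = 0.000638). In replicate 1's own list the COE odds ratio was 9.75 and the call was lost (interval 0.468 to 203, Fisher's exact p = 0.115); in replicate 2's it was 9.92 (interval 1.16 to 85.04, Fisher's exact p = 0.0185). The GATA pattern TGATAA was less frequent in peaks, 8.39% against 17.5% (odds ratio 0.430, Fisher's exact adjusted p = 3.92e-16), as was the PBX-HOX pattern (odds ratio 0.568, Fisher's exact adjusted p = 1.10e-07). The GC box (odds ratio 3.62), the E-box CAGCTG (1.45), the homeodomain pattern (0.505) and poly-T (0.433) also passed against flanks; the CAGCTG call was lost in replicate 1's own list (odds ratio 1.37, Fisher's exact p = 0.151). Peak windows held 44.8% GC and flanks 36.6%. Against windows matched on GC, those 4 patterns no longer passed, with odds ratios of 1.26, 0.850, 1.01 and 1.05, and the nuclear receptor pattern AGGTCA became less frequent in peaks (odds ratio 0.593, Fisher's exact adjusted p = 0.00253). Of all 6-mers, 660 were enriched; ranked by p, GAGAGA (37.7% of peaks, 11.8% of flanks) led, followed by AGAGAG (32.4% and 9.42%) and ACGCAG (22.2% and 4.39%). Against GC-matched windows 352 were enriched, 311 of them among the 660.

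**Figure D3:**
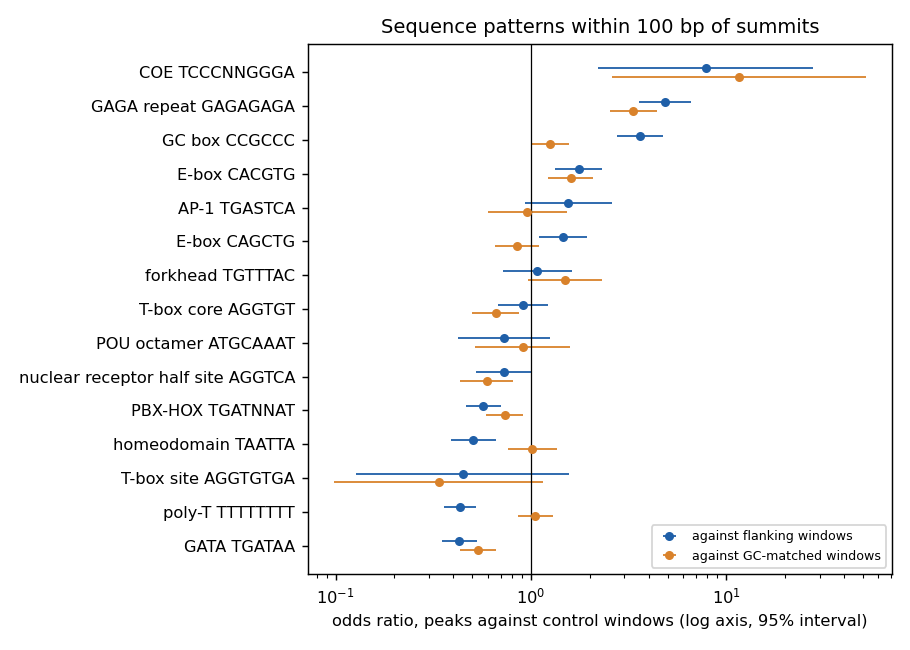
Odds ratio (x axis, log scale, with 95% interval) of each of 15 sequence patterns within 100 bp of the 1431 main summits, against flanking windows (blue) and GC-matched windows at genes without a peak (orange). The GAGA repeat lies above 1 against both, and the interval of the T-box site AGGTGTGA, 0.127 to 1.57 against flanks, spans 1.

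In the main list, ribosomal protein and pan-neuronal genes carried peaks more often than other genes, and chemoreceptor and F-box genes less often. The pan-neuronal call held in neither replicate's own list, and the F-box call was lost in replicate 1's. In all, 995 of 19973 protein-coding genes (4.98%) were bound, meaning that their start was the nearest to a main summit and within 2000 bp of it. Of 33 lists and families, 7 passed the test, 4 with more bound members and 3 with fewer.

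Among cytosolic ribosomal protein genes, 20 of 78 were bound (25.6%, odds ratio 6.69, interval 4.01 to 11.2, Fisher's exact adjusted p = 1.53e-08). The list also passed in each replicate's own list, with 14 and 16 bound members. The highest signals were at rpl-3 and rpl-35, followed by rpl-15 at 463 (219 and 234 in the replicates), with its summit 349 bp upstream, and rps-1 at 452 (249 and 205), 264 bp upstream.

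Of 29 pan-neuronal genes, 10 were bound (34.5%, odds ratio 10.1, interval 4.70 to 21.8, Fisher's exact adjusted p = 8.33e-06). Their signals were highest at unc-64, which encodes syntaxin (117, with 54.96 and 59.6 in the replicates), cab-1, ida-1 (103) and unc-104, a kinesin of synaptic vesicle transport (83.2). The unc-64 peak was in both replicates' thresholded lists, the cab-1 and ida-1 peaks were in replicate 1's only, and the unc-104 peak was in neither. The call was lost in both replicates' own lists, with 3 bound members in replicate 1 (odds ratio 3.60, Fisher's exact adjusted p = 0.398) and 4 in replicate 2 (odds ratio 4.73, Fisher's exact adjusted p = 0.0941), within 1000 bp of the start (odds ratio 3.70, Fisher's exact adjusted p = 0.127), and among the stronger peaks by signal (odds ratio 3.97, Fisher's exact adjusted p = 0.397).

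Axon guidance genes had 6 of 38 members bound (odds ratio 3.59), led by unc-115 (148), unc-76 (140), unc-51 (136) and unc-14 (80.1). The starved and early L1 genes had 5 of 27 bound (odds ratio 4.35), led by the heterochronic gene lin-28 (106), the AMP-activated kinase gene aak-2 (103), lin-41 (94.5) and lin-14 (87.7). Both had a Fisher's exact adjusted p of 0.04997, at the threshold, and neither passed in either replicate's own list or against lists matched on the length of nearest genome (permutation adjusted p = 0.462 for both). Neither passed within 1000 bp of the start (odds ratios 1.28 and 2.89, Fisher's exact adjusted p = 0.886 and 0.330) or among the stronger peaks by signal (2.94 and 2.74, Fisher's exact adjusted p = 0.509 and 0.690). The axon guidance call was also lost from 2000 bp upstream to the gene's end (odds ratio 2.24, Fisher's exact adjusted p = 0.193), and the starved and early L1 call in the other pooled list (odds ratio 3.24, Fisher's exact adjusted p = 0.191).

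Chemoreceptor genes were bound in 8 of 1293 cases (0.619%, odds ratio 0.112, interval 0.0555 to 0.224, Fisher's exact adjusted p = 3.10e-18), and this held in both replicates' own lists (odds ratios 0.114 in replicate 1's and 0.0642 in replicate 2's). The bound members with the highest signal were sri-5 (222), srh-16 (202), srh-2 (131) and srv-14 (109). F-box genes had 4 of 322 bound (odds ratio 0.237, Fisher's exact adjusted p = 0.00533), namely fbxb-58 (277), fbxb-85 (250), fbxa-65 (119.5) and fbxa-83 (109). This call was lost in replicate 1's own list (odds ratio 0.487, Fisher's exact adjusted p = 0.595) and among the stronger peaks by signal (odds ratio 0.427, Fisher's exact adjusted p = 0.509). C-type lectin genes had 3 of 240 bound (odds ratio 0.239, Fisher's exact adjusted p = 0.0264), namely clec-151 (94.1), clec-196 (82.7) and clec-170 (60.1). The clec-151 summit lay in an intron of pfas-1. The C-type lectin odds ratio was 0.0638 in replicate 1's own list, with 0 bound (Fisher's exact adjusted p = 0.0114), and 0.122 in replicate 2's, with 1 bound (Fisher's exact adjusted p = 0.04496). The C-type lectin call was lost against lists matched on the length of nearest genome (permutation adjusted p = 0.0950).

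The other 26 lists did not pass, with Fisher's exact adjusted p from 0.0901 to 1. Counting summits from 2000 bp upstream to the gene's end, 8 lists passed, among them 2 of these 26: heat shock proteins with 6 of 22 bound (odds ratio 4.48, Fisher's exact adjusted p = 0.0256) and collagens with 4 of 156 (odds ratio 0.311, Fisher's exact adjusted p = 0.0414). In the T-box family 1 of 22 members was bound, mab-9 itself, and 0 of 6 Hox genes were. Of 26 hindgut and male tail regulators 1 was bound, egl-27, through a summit in its intron (signal 101, with 52.7 and 49.0 in the replicates). Of 37 cholinergic motor neuron genes 4 were bound, led by twk-43 (155), mab-9 and twk-40 (65.1). Body wall muscle genes had 2 of 38 bound, sca-1 (89.5) and lev-1 (68.6), hypodermis and seam genes 1 of 38, lin-28, and intestine genes 0 of 31. These lists are small, and a missed threshold does not show that they were bound as often as other genes.

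**Figure D4:**
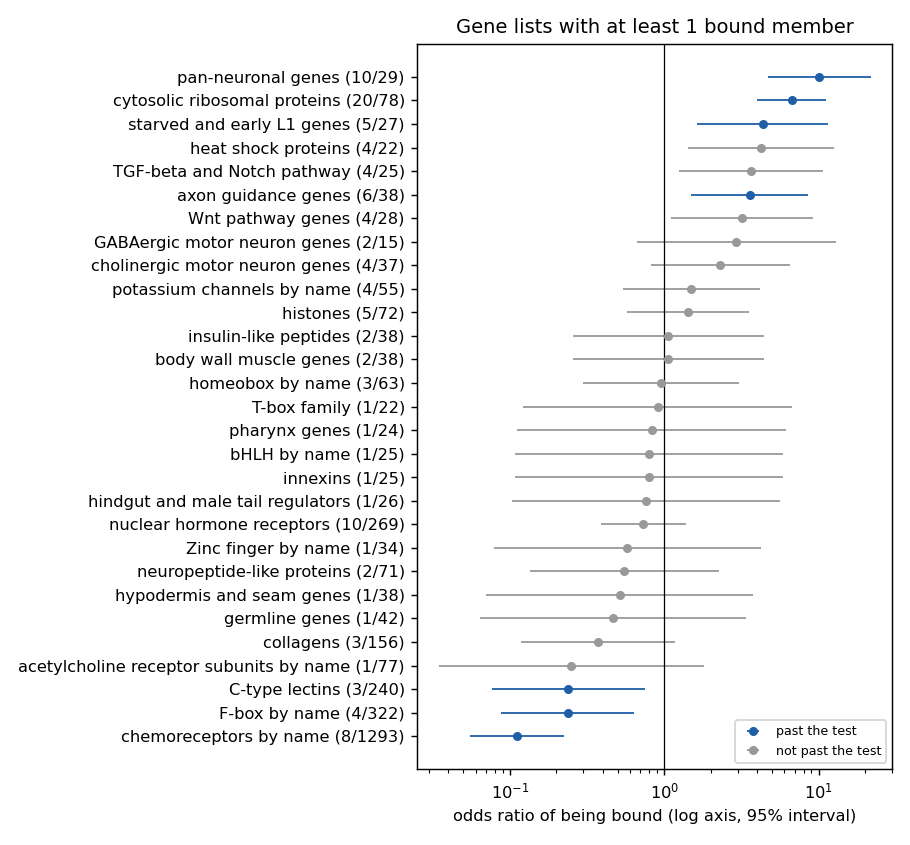
Odds ratio of being bound (x axis, log scale, with 95% interval) for each list with at least 1 bound member; bound members and list size are in parentheses, and the 4 lists with none bound are left out. Blue lists passed the test, with ribosomal protein genes at 6.69 and chemoreceptor genes at 0.112.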

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

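In data outside the main measurement, 83 peaks of the ranked list passed the reproducibility threshold and were absent from the conservative list. The strongest lay on chromosome X from 15811006 to 15811183 with a signal of 1808 (1183 and 786 in the replicates), above every main peak, and the next on X from 293346 to 293505 with a signal of 833. Only 6.02% of the 83 lay at promoters. Soft-masked (repeat) sequence covered 79.5% of the left-out peaks on average and 27.8% of the kept ones, a difference of 51.7 percentage points (bootstrap 95% interval 44.6 to 58.2, permutation p = 1e-05, the smallest that 100000 resamples can give).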

How the results depend on the processing

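The setting that leaves out main peaks overlapping a stronger one was chosen after seeing the data; the others were planned. The promoter share, the replicate overlap and the lack of detected AGGTGTGA enrichment kept their direction and side of the threshold under all alternatives run. The following moved or turned, and the cause was not tested unless stated. Requiring a peak in both replicates' own lists left 560 peaks, by construction. The Spearman rho between replicates was 0.636 over the other pooled list, outside the bootstrap interval of the main value. Enriched 6-mers numbered 352 against GC-matched windows, which also lie at other gene starts. Lists past the test numbered 3 for the stronger peaks by signal, 4 within 1000 bp and 4 against matched lists, and 3 to 4 in single replicates' own lists, where fewer genes were bound. The X share was 16.6% to 16.9% in single replicates' own lists, under the genome share, with no detectable difference in either setting. The median signal difference with AGGTGTGA was -16.57 for the stronger peaks and -3.99 to 9.59 in single replicates' lists, from at most 3 peaks with a site. Within 50 bp of the summit no peak held AGGTGTGA, so that difference could not be computed. Among single lists, 19 values kept their direction and no longer passed the test, and 37 held. No depth is known, so its effect on these lists could not be assessed.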

Other observations

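The tests of pull-down chromatin and of weak peaks, the scan of gene classes, the choice of AGACGCAG, the counts of spliced leader genes and the X promoter comparison with its tests by odds ratio were chosen after the results were seen; the other tests were set before the values they measure were seen.

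Peaks at RNA gene families were counted and the families were not tested against each other. Of 612 tRNA genes, 54 had a summit within 200 bp, as did 43 of 346 snoRNA genes, 4 of 261 miRNA genes, 16 of 15363 piRNA genes and 0 of 20 rRNA genes. SL2 spliced leader genes, whose RNA is trans-spliced onto downstream genes of operons, had a peak at 5 of 18, and SL1 spliced leader genes at 0 of 12. Reads shared between near-identical copies were not assessed. The highest SL2 signals were at sls-2.1 (523), sls-2.4 (489) and sls-2.2 (411). Among 175 gene classes by name with at least 10 members, 4 were bound more often in both the Fisher's exact and the matched test: unc (21 of 94), rpl (13 of 47), lin (11 of 47) and rps (7 of 31). The rpl and rps classes together are the ribosomal protein list above. Some bound unc genes were also counted in the pan-neuronal and axon guidance lists, so these classes are not separate evidence. The chemoreceptor classes str and srh were bound less often by the Fisher's exact test only.

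That no enrichment of AGGTGTGA was detected was weighed against 2 technical explanations. With 1 mismatch allowed the odds ratio was 0.806 (95% interval 0.646 to 1.005). For all variants with 1 mismatch pooled, this argues against a pattern that is merely too strict. It does not test single variants, a shorter site or a site of another shape. In 8561 ranked peaks below the threshold the odds ratio was 1.13 (interval 0.723 to 1.77), so enrichment in weaker peaks cannot be told apart from none with this few sites. No biological explanation was tested.

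Ranked by p, the word AGACGCAG led the 8-mers, in 182 peaks (12.7%) and 35 flanks (1.26%). Some other 8-mers, such as GCGCCAGC (25.15), had higher odds ratios than its 11.4. In the replicates' own lists the odds ratio of AGACGCAG was 8.998 and 12.1. Against GC-matched windows the odds ratio was 4.84 (95% interval 3.69 to 6.35), which argues against base composition as the whole cause. AGACGCAG lay in 3 of 68 peaks at ribosomal protein or tRNA genes (4.41%) and in 179 of 1363 other peaks (13.1%). The odds ratio was 0.305 (interval 0.0949 to 0.982, Fisher's exact p = 0.0380). In the pooled set the word was less frequent at those genes than in other peaks, with an upper limit close to 1 and few sites. With 68 peaks there and 182 peaks holding the word, they could not have been its only source whatever the result. The comparison therefore does not test pull-down chromatin as a cause. Neither kind of gene differed detectably alone. The word lay in 1 of 20 peaks at ribosomal protein genes (odds ratio 0.348, interval 0.0463 to 2.62, Fisher's exact p = 0.5005). It lay in 2 of 48 peaks at tRNA genes (odds ratio 0.288, interval 0.0692 to 1.195, Fisher's exact p = 0.0773). Chromatin that any pull-down recovers cannot be told apart as a cause without a control or another factor. That ribosomal protein genes were bound 5.66 times as often as matched lists (permutation p = 0.0002, the smallest that 10000 lists can give) was known beforehand and does not concern the word. No biological explanation was tested.

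Peaks on X lay at promoters less often than autosomal peaks, 43.1% against 58.4% (Fisher's exact p = 6.20e-06), and likewise in replicate 1 (41.6% and 65.2%) and replicate 2 (44.9% and 65.6%). The odds ratio was 0.539 (interval 0.412 to 0.705) where random placements gave 0.824 on average (permutation p = 0.0230). In the replicates' own lists it was 0.380 (interval 0.261 to 0.553, permutation p = 0.0240) and 0.426 (interval 0.298 to 0.611, permutation p = 0.0280), where their placements gave 0.8235 and 0.8202. In each list the interval lay under the mean of the placements. That rule was chosen after the results were seen, the stricter rules given below were missed, and the lists share peaks. Whether lower gene density of X is the whole cause therefore cannot be told, and it may account for part. Random placements of the main list gave a difference of -3.65 percentage points (95% range -8.88 to 1.57) where -15.35 was observed. That is 6.47 beyond the range and short of the margin of 10 set in advance. In the replicates' own lists the difference lay 12.3 (replicate 1) and 9.63 (replicate 2) percentage points beyond the range of their placements. Placements of the main list put 24.95% of all summits at promoters, against 55.6% of the peaks. Differences in percentage points are therefore on unlike scales and cannot decide on gene density. The main odds ratio of 0.539 also missed the stricter bound first set for it, an upper limit under the range of the placements (0.589 to 1.09). GCGCAGGG, a word of dosage compensation complex recruitment sites, lay in 17 X peaks and 0 autosomal peaks (odds ratio 162.7 with a constant added for the 0, interval 9.75 to 2715, Fisher's exact p = 2.63e-13). Such sites may carry some X peaks. Peaks with this exact word were 6.37% of X peaks, and without them the promoter share on X was 44%, so those peaks leave most of the difference open. Recruitment sites without the exact word were not counted, so the share of the difference due to all such sites cannot be told. No other biological explanation was tested.

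All 25 main peaks with a signal under 10 overlapped a stronger main peak (100%), against 3.27% of the other peaks.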
